A study of Mus musculus with 6 samples.

How the data were processed

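RNA-seq of sorted long-term hematopoietic stem cells (lineage-negative, Sca-1-positive, c-Kit-positive, CD48-negative, CD150-positive bone marrow cells) was available for 6 libraries from female mice aged 8 weeks. They comprised 3 libraries of genotype c-Myc floxed/+ (WT) and 3 of the same genotype with the Mx1-Cre transgene (HET). Groups were taken from the genotype label of each sample and library numbers (1, 3 and 4) from its title. The titles call the HET libraries knockouts, and the genotype label was followed.

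The authors deposited a table of whole-number read counts per gene and library. FastQC, STAR 2.5.2b, edgeR, limma and the mm10 build are named in the submitters' processing notes, which give them no role or order. The read counter, gene annotation, strand setting and library kit are not given in the sources used here, because the protocol fields attached to these samples describe material of another study and were not used. How reads from paralogs, pseudogenes and overlapping genes were assigned is therefore open, and values of such genes (the Gbp genes, ribosomal protein genes, Pvt1 and its neighbours) are uncertain. The deposited table held counts for 11779 genes. Each exceeded 1 CPM (counts scaled to a common library total) in at least 2 libraries (the lowest second-highest value was 1.012), so the table had been filtered on low counts before deposit. It listed 0 mitochondrially encoded genes, and 11380 of its genes were protein-coding and 325 non-coding RNAs by the naming table used. Date-like entries produced by spreadsheet software were mapped back to 18 gene symbols. Positions, exonic lengths and GC content came from GENCODE M21 on GRCm38, the assembly also called mm10, and were found for 11775 genes. Gene lists used 4 genes matched by an older symbol.

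Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which removed 910 and left 10869. Library sizes were scaled by TMM, dispersions were estimated robustly, and HET was compared with WT by the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The group was the only term in the model. The biological coefficient of variation was 20.7%. Levels are CPM on the TMM-scaled library size, given as mean ± SD of 3 libraries. Standard errors of log2 fold changes were derived from the F statistic. For Myc an exact permutation test was added, whose smallest p in this design is 0.1. For genes with few counts, ratios of pooled counts carry exact 95% intervals, which cover counting error only, since reads were not collapsed by molecular identifiers. A count of 3 corresponded to between 0.298 and 0.715 CPM, depending on the library.

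Before the data were examined, 38 gene lists were written. They covered the MYC network, growth and metabolism, the cell cycle, stress and signalling responses, stem cell identity and markers of other marrow cells. Of these, 36 had at least 5 tested members. The lists of mitochondrially encoded and B lineage genes had fewer and were not tested. Lists were tested with limma 3.58.1 (camera on voom values with a preset inter-gene correlation of 0.01), adjusted over the 36 lists. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance without comparing them with other genes. Several lists share members, and Btg2 is in 3 of the called or named groups. The rule for named genes was also fixed then. It took Myc and the measured members of its network, and the 10 higher and 10 lower genes of smallest p past the threshold with an average log2 CPM of at least 2 and no overlap between the groups, leaving out predicted genes. Where fewer than 5 in a direction qualified, the next gene was added and said not to pass. It also took up to 4 genes of smallest p per list. Genes outside the rule, among them Fos, Egr3, Socs3, Jun, Dusp1, the remaining called genes, the clock genes, the RNA polymerase III transcripts, Trib1 and Metap1, were chosen after their values were seen. Some results for single genes are not reported here.

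The design written in advance covered RLE and upper quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with and without library weights, the library number as a block, other thresholds, and leaving out each library in turn. After seeing the data, HET 1 was thinned to the mean depth of the other libraries, non-coding genes were left out, and the trend of each library with exonic length and GC was removed (natural splines with 4 degrees of freedom). The scripts were tested on simulated counts drawn from the means, dispersions and depths of these libraries, with 200 genes changed in each of 5 simulations and a mean of 10727 genes tested. Of 572 calls, 30 (5.24%) were false. A list shifted by 0.4 log2 units was called in 5 of 5 simulations, in which 2 calls of other lists were also made. With no list shifted there were 0 calls in 176 tests. Simulated genes were drawn independently, so these counts do not give the rate of false calls for lists whose genes are correlated. In the real libraries the estimated correlation was 0.126 for the cytosolic ribosomal proteins and 0.764 for the DNA replication genes.

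Total counts ranged from 4249490 to 9886223 per library. Spearman correlations between libraries lay between 0.964 and 0.978 across genes. Libraries of a group differed by more than counting noise (chi-square per degree of freedom from 8.29 to 27.7), so no 2 libraries had the same counts; this does not show whether they came from separate mice. HET 1 was the deepest library and had the lowest estimated quality weight, 0.446.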

Results

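Long-term hematopoietic stem cells are the rare bone marrow cells that sustain blood production over a lifetime. RNA-seq profiles of these cells were compared between 2 groups of female mice aged 8 weeks. Both groups carried 1 floxed allele of Myc, the gene of the growth-regulating transcription factor c-MYC. The WT group (n = 3 libraries) had no Cre recombinase, and the HET group (n = 3) carried Mx1-Cre, a transgene in which the interferon-responsive Mx1 promoter drives Cre. Deletion of the floxed allele was induced with 3 injections of the double-stranded RNA analog poly(I:C) at 6 mg/kg, and the design text does not say separately whether WT mice were injected. Cells were sorted as negative for lineage markers and CD48 and positive for Sca-1, c-Kit and CD150. The libraries were numbered 1, 3 and 4 in each group, and their titles call the HET libraries knockouts although the genotype label is heterozygous. Total counts were 5512100, 5600856 and 4249490 in WT 1, 3 and 4, and 9886223, 4627452 and 5054028 in HET 1, 3 and 4. The 5 most abundant genes (Rn7sk, Rpph1, Malat1, Rmrp and Hsp90ab1) held 6.70% ± 0.80 of the counts in WT and 6.28% ± 1.17 in HET (SD, n = 3 each).

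The first question was how far the Myc transcript differed in HET, where deletion of 1 allele was induced. Deletion itself was not measured here. Myc (ENSMUSG00000022346; GRCm38 chromosome 15, 61985391 to 61990374, plus strand) measured 447.4, 427.4 and 541.8 CPM (counts scaled to a common library total) in WT 1, 3 and 4, and 293.8, 386.7 and 372.0 CPM in HET 1, 3 and 4. Every HET library lay below every WT library, with means of 472 ± 61.1 CPM in WT and 351 ± 49.9 CPM in HET (SD, n = 3 each). The edgeR quasi-likelihood fit put HET at 74.2% of the WT level (95% interval 62.1% to 88.8%), a log2 fold change of -0.43 with a standard error of 0.12. As the single gene named in advance for this question, Myc had an unadjusted p of 0.00235 in edgeR, and it passed when adjusted over the MYC network list alone, but its p adjusted over all 10869 genes tested was 0.312. The exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it allows. These are counts for the whole gene, so reads from any part of the transcript outside the floxed segment are included. Mycn, which encodes the related factor N-MYC, measured 301 ± 45.7 CPM in WT and 408 ± 119 CPM in HET (SD, n = 3 each), with overlapping libraries, a log2 fold change of 0.44 ± 0.22 (SE) and an edgeR adjusted p of 0.979. The overlap came from HET 1, at 271.5 CPM against 469.3 and 484.0 CPM in HET 3 and HET 4. Without HET 1, Mycn was higher in HET by 0.66 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 0.00297), while in the other 5 fits that left out 1 library it did not pass, with log2 fold changes from 0.30 to 0.52.

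Of the 12 tested members of the MYC network list, which holds the MYC proteins, their partner Max and related factors, none passed over all genes tested in the fit of all 6 libraries and 1, Myc, passed when adjusted over the list alone. The list's median log2 fold change was -0.11, and its camera test gave an adjusted p of 0.129. Max, the obligate partner of MYC, had a log2 fold change of 0.07 ± 0.13 (SE). The antagonists of the MXD and MNT type had values of -0.23 for Mnt, -0.26 for Mxi1, -0.16 for Mxd1, -0.14 for Mxd3 and -0.11 for Mxd4, with standard errors from 0.12 for Mnt to 0.41 for Mxd3. Mga had 0.15, Mlx -0.07, Mlxip -0.09 and Zbtb17, which encodes the MYC partner MIZ-1, -0.11.

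**Figure D1:**
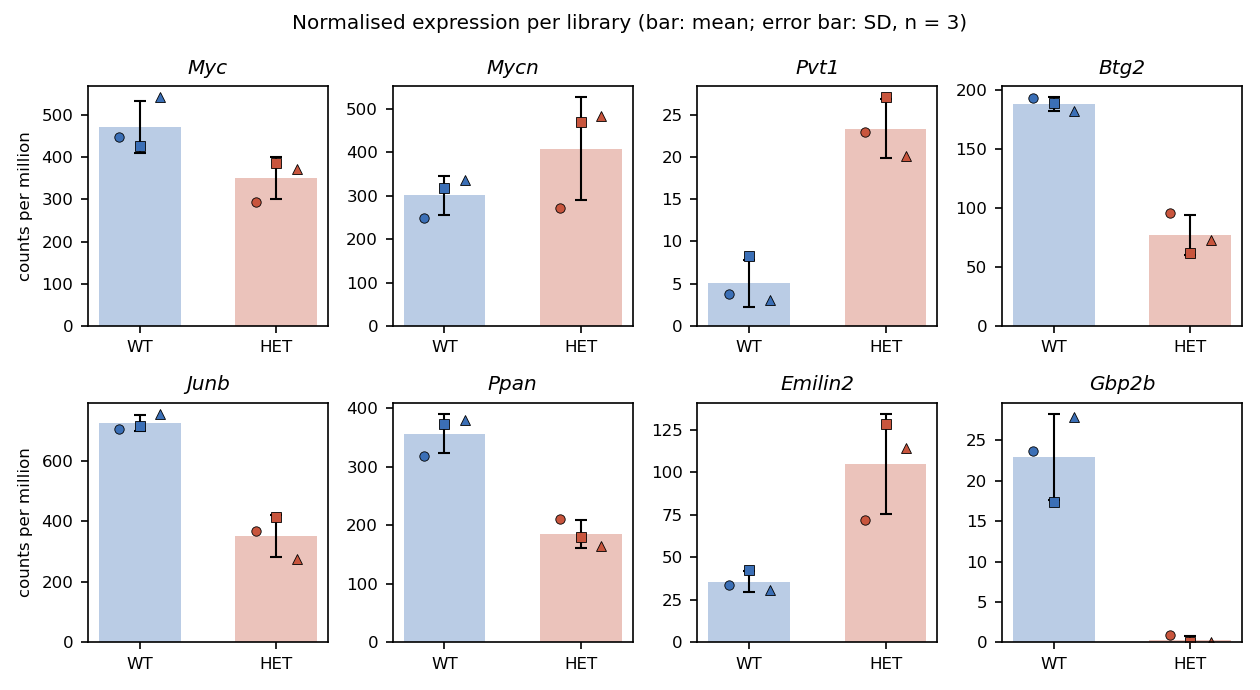
Normalised expression in CPM (vertical axes, starting at 0) of 8 genes in the WT (blue) and HET (red) libraries; bars are means, error bars SDs (n = 3), and circles, squares and triangles are libraries 1, 3 and 4. Myc averaged 472 CPM in WT and 351 CPM in HET, and Gbp2b 23.0 and 0.298 CPM; the groups do not overlap for any of the 8 genes except Mycn.

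The second question was which genes changed across the transcriptome. Of 10869 genes tested with edgeR, 28 passed an adjusted p of 0.05, 4 of them higher and 24 lower in HET. An unadjusted p under 0.05 was reached by 567 genes, where chance alone would give 543. The 4 higher genes rose between 1.83-fold and 4.56-fold, and the 24 lower genes, Gbp2b aside, fell between 1.5-fold and 3.27-fold. The count was 11 without WT 1, 68 without HET 1 and 10 without HET 4.

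The gene with the smallest adjusted p among the higher genes was Emilin2, which encodes an extracellular matrix glycoprotein. It rose from 35.7 ± 6.24 CPM in WT to 105 ± 29.3 CPM in HET (SD, n = 3 each), a log2 fold change of 1.54 ± 0.21 (SE, edgeR adjusted p = 0.00116). Vmp1, which encodes a membrane protein needed for autophagosome formation, rose by 0.87 ± 0.14 on the log2 scale (adjusted p = 0.00531). Pvt1, a long non-coding RNA gene (ENSMUSG00000097039; chromosome 15, 62037986 to 62378096, plus strand) that starts 47.6 kb downstream of Myc, rose from 5.04 ± 2.79 to 23.3 ± 3.51 CPM (SD, n = 3 each), a log2 fold change of 2.19 ± 0.38 (SE, adjusted p = 0.00725). Amn1 rose from 12.2 ± 2.78 to 33.7 ± 6.99 CPM (log2 fold change 1.46 ± 0.28 SE, adjusted p = 0.0203). Txnip, which encodes the thioredoxin-interacting protein, was next in rank with 581 ± 74.8 CPM in WT and 884 ± 159 CPM in HET and did not pass over all genes (adjusted p = 0.0672), although it passed without HET 1 (log2 fold change 0.74, adjusted p = 1.752e-04). Without WT 1, the adjusted p was 0.0873 for Pvt1 and 0.0548 for Vmp1. Vmp1 also missed the threshold without WT 3 (0.0521), without HET 4 (0.0799) and with the length and GC trend removed (0.0829), and Pvt1 (0.0542) and Amn1 (0.106) missed it with limma-voom. Amn1 missed it without WT 1 (0.0873), WT 3 (0.147), HET 3 (0.118) or HET 4 (0.128), while Emilin2 passed in each fit that left out 1 library.

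Gbp2b, which encodes an interferon-inducible guanylate-binding GTPase (ENSMUSG00000040264; chromosome 3, 142594847 to 142619179, plus strand), was nearly absent from HET. It had 131, 95 and 117 counts in WT 1, 3 and 4, and 9, 0 and 0 counts in HET 1, 3 and 4 (edgeR adjusted p = 1.679e-04). Scaled for library size, the pooled HET counts were 2.01% of the WT counts (exact 95% interval for counting error 0.913% to 3.87%). Gbp2b lies among closely related paralogs and the read counting is not given in the sources used here, so its level is uncertain. Gbp2, the adjacent gene, measured 78.4 ± 3.14 CPM in WT and 108 ± 13.4 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.495).

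Another 9 of the genes named by smallest p were lower in HET. Btg2, an antiproliferative gene, fell from 188 ± 5.55 to 76.9 ± 17.1 CPM (SD, n = 3 each; log2 fold change -1.28 ± 0.15 SE; edgeR adjusted p = 1.679e-04). Junb, which encodes an AP-1 subunit, fell from 725 ± 26.8 to 352 ± 69.0 CPM (log2 fold change -1.04 ± 0.12 SE; adjusted p = 1.948e-04). Ppan, a ribosome biogenesis factor, fell by 0.94 on the log2 scale (adjusted p = 5.214e-04). The transcription factor gene Cebpb fell by 1.34 (0.00207) and Rgs2, a regulator of G protein signalling, by 1.19 (0.00284). Plk2, which encodes a polo-like kinase, fell by 1.40 (0.00494), Smad7, an inhibitor of TGF-beta signalling, by 0.95 (0.00494), Maff, a small MAF factor, by 1.20 (0.00511) and D8Ertd738e by 0.82 (0.00531). Btg2, Junb, Ppan, Cebpb, Rgs2 and Gbp2b also passed in all 6 fits that left out 1 library. Without WT 1, Plk2 (adjusted p = 0.0548), Smad7 (0.0548) and Maff (0.0626) did not, and without HET 4 the values were 0.0530 for Plk2, 0.0799 for Smad7, 0.0753 for Maff and 0.117 for D8Ertd738e. D8Ertd738e had 0.0635 without WT 3 and 0.125 with the length and GC trend removed. The remaining lower genes included Hk2, Fosl2, Fzd4, Tob2, Dgat1, Nkx2-3, Crem, Ccnt1, Per1, Ppp1r15a, Dhrs11, Irs2 and A930011G23Rik. None of these passed in all 6 fits that left out 1 library: Hk2 and Fosl2 missed the threshold in 1, Dgat1 in 2, Fzd4, Irs2, Nkx2-3 and Per1 in 3, Ccnt1, Crem, Dhrs11, Ppp1r15a and Tob2 in 4 and A930011G23Rik in 5.

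**Figure D2:**
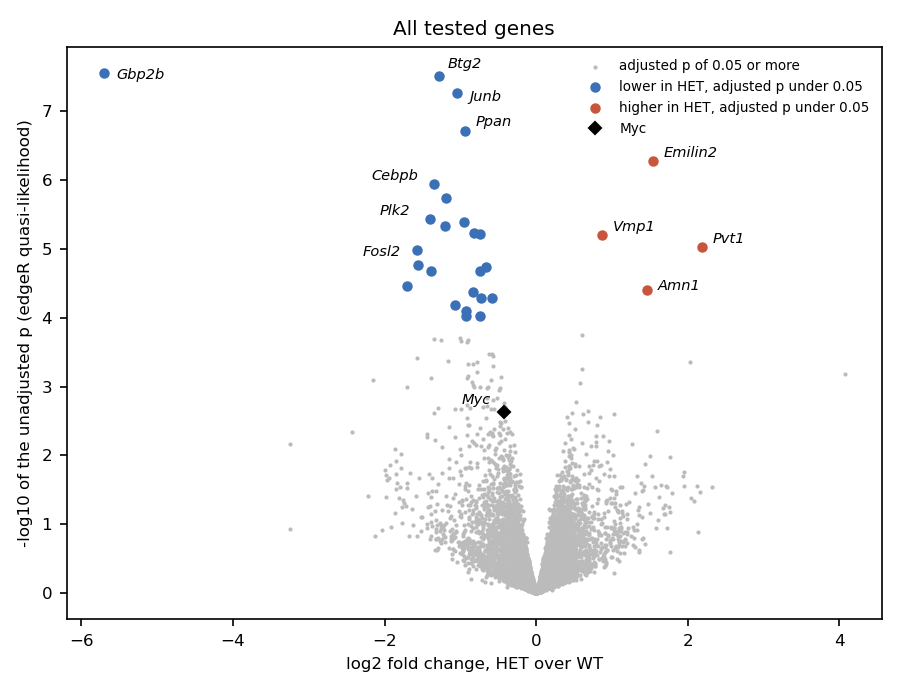
Each point is 1 of the 10869 tested genes, with its log2 fold change (HET over WT) on the horizontal axis and the -log10 of its unadjusted edgeR p on the vertical axis; colored points have an adjusted p under 0.05 and the diamond is Myc. Of the 28 colored genes, 24 lie on the lower side, with Gbp2b farthest out at -5.71.

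The third question was whether gene groups fixed before the data were examined moved together. Of 36 lists with at least 5 tested members, camera with a preset inter-gene correlation called 10, of which 3 were higher and 7 lower in HET. With the correlation estimated from these libraries 0 lists passed, although camera still gave 3 of the lists named here unadjusted p-values of 0.00445 for the immediate early genes, 0.0124 for the p53 targets and 0.0346 for the cytosolic ribosomal proteins. The self-contained test fry called 2 lists.

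Immediate early genes, which respond within minutes to growth factor and stress signals, were the group with the smallest camera p. By fry this group did not pass (adjusted p = 0.135). Of 32 tested members of the list of immediate early and MAP kinase feedback genes, 4 fell over all genes tested (Btg2, Junb, Maff and Fosl2), 0 rose and 28 did not pass. When adjusted over the list alone 7 fell, adding Socs3, Egr3 and Fos. The median log2 fold change was -0.43 (camera adjusted p = 1.848e-15), and the adjusted p with an estimated correlation was 0.160. Fosl2, which encodes an AP-1 subunit, fell from 605 ± 147 to 203 ± 44.1 CPM (SD, n = 3 each; edgeR adjusted p = 0.00751), and its adjusted p was 0.0734 without HET 3 and 0.175 with the length and GC trend removed. Fos measured 1392 ± 266 CPM in WT and 904 ± 196 CPM in HET, and Nr4a1 1315 ± 227 and 334 ± 224 CPM, without passing over all genes. Members did not all lie on the lower side: Jun had a log2 fold change of 0.35 ± 0.51 (SE) and Dusp1, a MAP kinase phosphatase, 0.20 ± 0.45 (SE). The mean log2 level of the list was -0.65, -0.50 and -0.82 in HET 1, 3 and 4 relative to the WT mean, against -0.03, -0.03 and 0.06 in WT 1, 3 and 4. In 40.6% of its members (12 lower and 1 higher) the 3 HET libraries did not overlap the 3 WT libraries, against 10.3% over all genes. Chance gives 10% for a single gene, but members of a list can move together.

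Of 25 tested p53 targets, 2 fell (Btg2 and Plk2) and 3 fell when adjusted over the list alone, adding the death receptor gene Tnfrsf10b. The median was -0.08, the camera adjusted p was 6.294e-04, and the adjusted p was 0.224 with an estimated correlation and 0.0291 by fry. The list's median was -0.12 without HET 1 and -0.18 without HET 4. Cdkn1a, the cell cycle inhibitor p21, measured 46.7 ± 16.3 CPM in WT and 17.1 ± 12.2 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.788). Btg2 belongs to both this list and the immediate early list, and 7 of the 25 tested members are in other lists too. The list's mean log2 fold change was -0.29, farther from 0 than its median, with 19 negative and 6 positive values.

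Of the lists for the translation machinery, 2 were called lower in HET and 2 were not called. Of 72 tested cytosolic ribosomal protein genes, 58 had negative and 14 positive fold changes, and 0 passed in edgeR either over all genes or over the list alone. Their median log2 fold change was -0.24 (camera adjusted p = 7.086e-13; adjusted p = 0.415 with an estimated correlation). In this list 22 members, 30.6%, had all HET libraries below all WT libraries and 0 had them above. Over all genes 10.3% had no overlap in either direction. The smallest p was that of Rpl41, with 696 ± 69.8 CPM in WT and 507 ± 72.1 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.157). Ribosomal protein genes have many processed pseudogenes with near-identical sequence, so single members are uncertain. The list level was -0.25, -0.24 and -0.27 in HET 1, 3 and 4, and -0.16, 0.11 and 0.05 in WT 1, 3 and 4. Of 63 ribosome biogenesis genes 1, Ppan, fell, with 357 ± 33.7 CPM in WT and 186 ± 23.6 CPM in HET (SD, n = 3 each). The median was -0.09 (camera adjusted p = 0.00224; adjusted p = 0.669 with an estimated correlation), and the list missed the threshold without HET 3 (median -0.05, 0.123) or HET 4 (median -0.05, 0.125). HET 1 was not lower in this list: the levels were 0.02, -0.22 and -0.19 in HET 1, 3 and 4, and 0.00, 0.02 and -0.03 in WT 1, 3 and 4. Without HET 1 the median was -0.18 (camera adjusted p = 2.747e-09). Fbl, the rRNA methyltransferase fibrillarin, had a log2 fold change of -0.52 ± 0.21 (SE) and did not pass. Translation factors and tRNA synthetases (43 genes, median -0.04, camera adjusted p = 0.137) and mitochondrial ribosomal proteins (57 genes, median -0.01, 0.650) were not called. Without HET 1 the median of the translation factors was -0.13.

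The 20 tested cholesterol synthesis genes had a median log2 fold change of -0.31, and 18 of the 20 values were negative (camera adjusted p = 2.568e-05; adjusted p = 0.599 with an estimated correlation). Insig1, a sterol-responsive regulator of the pathway, measured 55.3 ± 7.13 CPM in WT and 37.4 ± 8.97 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.696). Without WT 3, whose list level was 0.37 above the WT mean, the list's median was -0.09 and its adjusted p 0.0725. Of 38 chaperone and unfolded protein response genes 1 fell, Ppp1r15a (GADD34), which directs dephosphorylation of the initiation factor eIF2-alpha, from 882 ± 77.7 to 588 ± 96.6 CPM (SD, n = 3 each; edgeR adjusted p = 0.0236). The median was -0.09 (camera adjusted p = 0.0266; adjusted p = 0.842 with an estimated correlation). Neither call held without HET 4, where the adjusted p was 0.390 for Ppp1r15a and 0.125 for the list, or without WT 3 (0.170 and 0.767). The list's median lay between -0.15 and -0.01 in the fits that left out 1 library, lowest without HET 1 and highest without WT 3. The list also missed the threshold without HET 3 (0.333), and Ppp1r15a without WT 1 (0.0543) or WT 4 (0.233).

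Type I interferon genes respond to poly(I:C). Of the 49 tested members of this list 36 had positive fold changes, 0 passed in edgeR over all genes or over the list alone, and the median was 0.15 (camera adjusted p = 6.294e-04; adjusted p = 0.637 with an estimated correlation). Zbp1, a nucleic acid sensor, measured 18.5 ± 1.34 CPM in WT and 32.0 ± 7.52 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.517). Mx1, whose promoter drives the Cre transgene, measured 3.53 ± 0.996 and 10.7 ± 5.48 CPM (0.450). Without WT 3 the list's adjusted p was 0.0571, and without WT 1 its median was 0.24. Of 23 megakaryocyte and platelet genes 21 had positive fold changes, 0 passed over all genes, and 1, the integrin gene Itga2b (CD41), passed over the list alone, with 289 ± 26.5 CPM in WT and 438 ± 107 CPM in HET (SD, n = 3 each). The median was 0.20 (camera adjusted p = 6.294e-04; adjusted p = 0.599 with an estimated correlation). This call rested on HET 1, whose list level was 0.59 above the WT mean, and without that library the median was 0.01 and the adjusted p 0.308.

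Of 51 genes of stem cell identity, 0 passed over all genes and 1, Txnip, was higher when adjusted over the list alone. The median was -0.09 (camera adjusted p = 0.00385; adjusted p = 0.648 with an estimated correlation), and without HET 1 the median was 0.01 and the adjusted p 0.915, while without WT 4 they were -0.04 and 0.117. The median was -0.06 without WT 1 and -0.15 without HET 3. Nr4a1 and Nr4a2, nuclear receptor genes that also belong to the immediate early list, had the largest negative values among the members named here, -1.97 ± 0.56 and -1.74 ± 0.64 (SE). Of 43 DNA replication genes 0 passed over all genes or over the list alone, with a median of 0.08 (camera adjusted p = 0.0163; adjusted p = 0.918 with an estimated correlation). HET 1 stood apart in this list, at 0.53 above the WT mean, against -0.26 in HET 3 and -0.15 in HET 4. Without HET 1 the list was called in the opposite direction, with a median of -0.20 (adjusted p = 6.942e-06), and it missed the threshold without WT 1 (0.104) or WT 4 (0.134). The median was 0.14 without WT 3, 0.24 without HET 3 and 0.17 without HET 4. In the list of G2 and mitosis genes, which was not called (49 genes, median 0.05, adjusted p = 0.417), HET 1 was 0.40 above the WT mean and HET 3 0.52 below it (a level of -0.52).

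**Figure D3:**
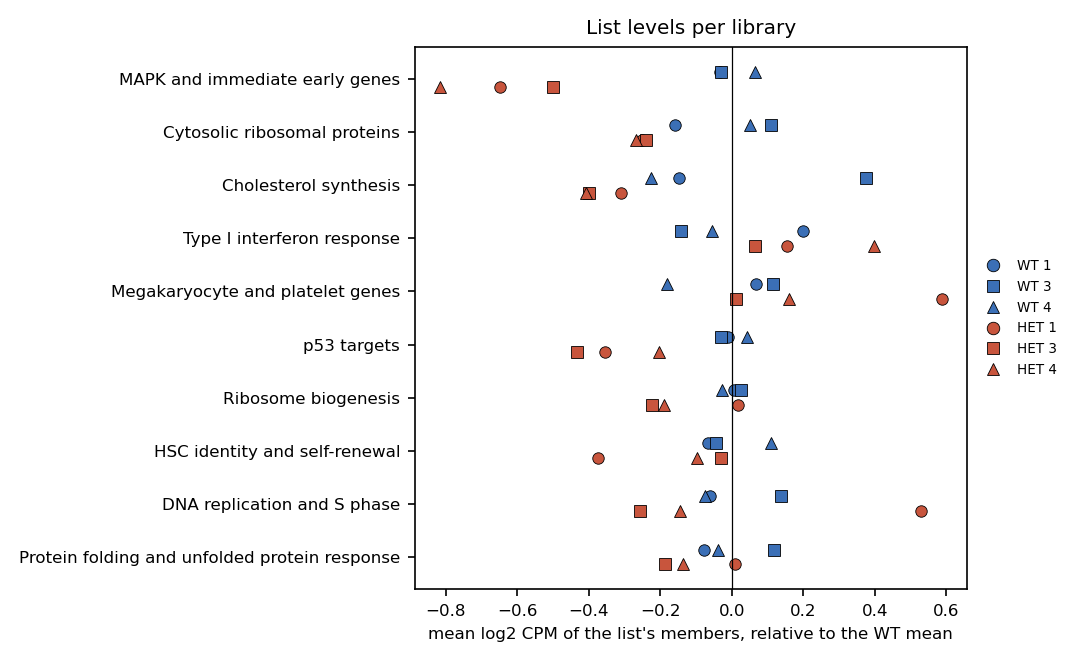
Mean log2 CPM of the members of each of the 10 called lists in each library, relative to the mean of the WT libraries (horizontal axis, log2 units); colors give the group and symbols the library number. All HET libraries lie below all WT libraries for the immediate early, ribosomal protein, cholesterol and p53 lists, while HET 1 lies apart from HET 3 and HET 4 in the DNA replication list (0.53, -0.26 and -0.15).

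Markers of other marrow cells were low or did not pass. Neutrophil genes (14 genes, median -0.31, camera adjusted p = 0.872) varied most between libraries, from -1.38 in WT 4 to 1.21 in WT 3 relative to the WT mean, and their median was 0.62 without WT 3 and 0.07 with limma-voom. Monocyte, macrophage and dendritic genes (15 genes, median -0.21, 0.650), T and NK genes (10 genes, median -0.11, 0.876), erythroid genes (17 genes, median 0.14, 0.612), endothelial and stromal genes (10 genes, median 0.07, 0.768) and multipotent progenitor genes (15 genes, median 0.005, 0.876) were not called. The monocyte median was 0.06 without WT 1 and the erythroid median 0.01 without HET 4. Cd48, whose protein was used to exclude cells in the sort, measured 2.55 ± 0.806 CPM in WT and 6.97 ± 2.88 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.849). The mast cell, basophil and eosinophil list (5 genes, median 0.14, 0.184) was not called, and Cpa3, a mast cell carboxypeptidase, had 3 counts over the WT libraries and 75 over the HET libraries, a ratio of 19.2 (exact 95% interval for counting error 6.32 to 95.2; edgeR adjusted p = 0.149 over all genes, passing over the list alone).

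The other lists were not called by camera. Hk2, a hexokinase, fell from 258 ± 22.2 to 155 ± 14.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.00531, and 0.0548 without WT 1) within a glycolysis list of 21 genes with a median of -0.11 (camera adjusted p = 0.345). Smad7 was the only called gene among 20 in the TGF-beta list (median 0.03, 0.199) and Btg2 among 19 cell cycle inhibitors and G1 regulators (median 0.03, 0.698). In the glycolysis, TGF-beta, cell cycle inhibitor, mitochondrial ribosome, hypoxia and multipotent progenitor lists, the median, mean and test differed in sign. No member passed over all genes in the lists for adhesion and niche retention (27 genes, median 0.12, camera adjusted p = 0.0537, fry adjusted p = 0.0437), NF-kB and inflammation (18, -0.10, 0.0635), autophagy and lysosome (30, -0.03, 0.109), polyamine synthesis (10, -0.11, 0.129), oxidative phosphorylation (59, -0.07, 0.184), DNA repair (45, 0.02, 0.199), MHC class II (8, 0.20, 0.356), replication-dependent histones (20, -0.17, 0.417), RUNX factors (7, 0.02, 0.731), hypoxia and redox (24, 0.02, 0.872), nucleotide synthesis (27, -0.06, 0.872) and apoptosis (27, 0.08, 0.876). The histone median was 0.10 without WT 3, 0.03 without HET 3 and 0.16 with the length and GC trend removed, the MHC class II median 0.006 without HET 4, the adhesion median 0.05 and the NF-kB median 0.07 without HET 1. The sign of the median also turned on 1 library in the lists for G2 and mitosis, cell cycle inhibitors, TGF-beta, RUNX factors, DNA repair, apoptosis, hypoxia, nucleotide synthesis, oxidative phosphorylation, the mitochondrial ribosome, multipotent progenitors and endothelial genes. The glycolysis median was -0.04 without WT 4, the polyamine median -0.23 without WT 3 and the autophagy median -0.10 without WT 1. Among the lists not called, only the MYC network kept its median within a factor of 1.5 in each fit that left out 1 library. Over the list alone, Tnfaip3, Tnfaip2 and Icam1 passed on the lower side in the NF-kB list, Vegfa in the hypoxia list and Impdh2 in the nucleotide list, and Itga2b passed on the higher side in the adhesion list and Hk3 in the glycolysis list.

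**Figure D4:**
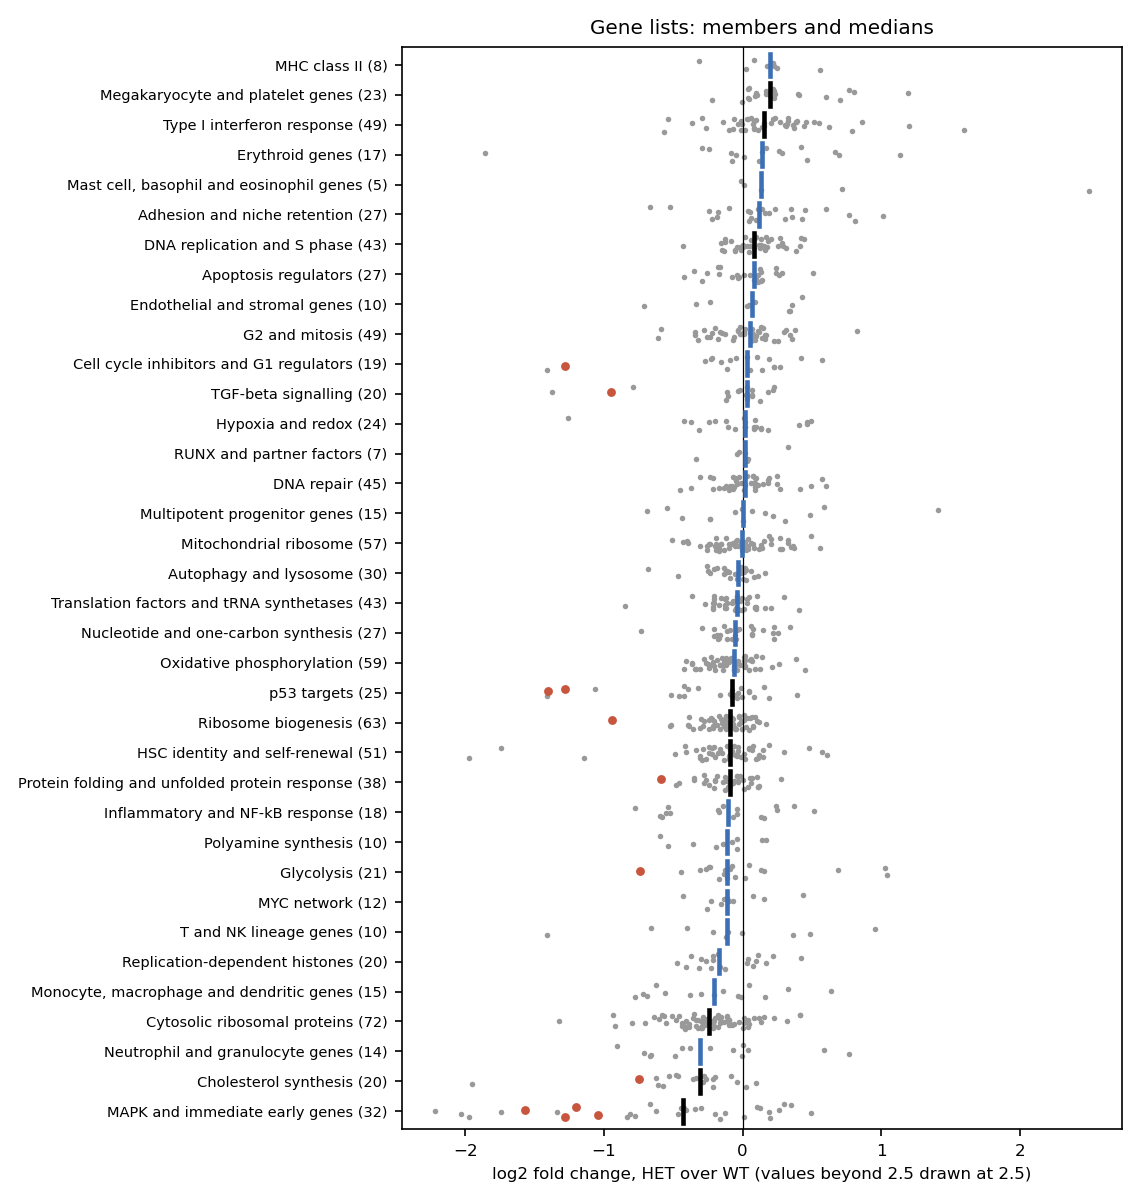
Log2 fold changes (HET over WT, horizontal axis) of the tested members of all 36 lists, ordered by median, with the number of tested members in brackets; red points have an adjusted p under 0.05 over all genes, and vertical bars are medians, black where camera called the list and blue where it did not. The lowest median is that of the immediate early list, -0.43, and 4 of its members are red.

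In simulated counts with the spread of these libraries, the same test found 19.7% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 86.8% of those changed 4-fold, so many changes of the size seen for Myc would be missed over all genes. No label states whether the libraries of a group came from separate mice or pools, so the p-values measure the spread between these libraries.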

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

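Myc stayed lower in HET with an unadjusted p under 0.05 in all alternatives, with log2 fold changes between -0.32 and -0.50 in the fits that left out 1 library. The 28 calls (4 higher, 24 lower) were 59 with DESeq2 (8 higher, 51 lower), 15 when a log2 fold change of at least 1 was also required (12 lower), and 23 with limma-voom, where 2 were higher. Limma-voom kept 18 of the 28 and added 5; those lost included Pvt1, Amn1, Fzd4, Dgat1, Crem, Ccnt1, Irs2, Dhrs11 and A930011G23Rik. Library weights lost Irs2, Dgat1 and Dhrs11, and the block lost Irs2. RLE and upper quartile scaling, the absence of a filter, a stricter filter and thinned HET 1 counts kept all 28 calls, and 24 remained after the length and GC trend was removed. Of the 4 lost there, Fosl2 (log2 fold change -1.57 ± 0.19 SE before, -1.56 ± 0.27 after), Vmp1 (0.87 ± 0.14, 0.85 ± 0.17) and Dhrs11 (-1.07 ± 0.21, -1.04 ± 0.23) kept their fold change with a larger standard error, while that of D8Ertd738e shrank (-0.82 ± 0.14, -0.59 ± 0.15). Without non-coding genes, Pvt1 and A930011G23Rik left the list because they were not tested. Fits that left out 1 library called between 10 and 68 genes, with 2 to 16 higher and 8 to 52 lower, and 7 genes passed in all 17 alternative fits run per gene. The cause of these differences was not tested. Leaving out a library lowers the number of libraries, yet without HET 1 the count was 68, above 28. The library numbers 1, 3 and 4 recur in both groups, but nothing in the labels says that they mark littermates or a day, and deviations of same-numbered libraries correlated at 0.11, -0.04 and 0.07. With the number as a block, 49 genes passed (44 lower), and the libraries did not each correlate best with their own number. Mycn passed in 1 alternative, without HET 1 (log2 fold change 0.66, adjusted p = 0.00297), and Txnip passed without HET 1, with DESeq2, with library weights and without a filter. Among 4 MYC network genes that did not pass in any fit, the log2 fold change over the fits that left out 1 library ran from -0.27 to 0.011 for Mxd1 (the latter without WT 1), from -0.18 to 0.022 for Mlxip (without HET 1), from -0.37 to 0.040 for Mxd3 (without HET 4) and from -0.19 to 0.062 for Mlx (without WT 4, and 0.031 without HET 4).

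Of the 10 called lists (3 higher, 7 lower), 0 passed with an estimated correlation (0 higher, 0 lower) and 1, the p53 targets, passed by fry. Over all 36 lists fry called 2 (1 higher, 1 lower), the other being adhesion and niche retention, which camera did not call. Fits that left out 1 library called between 9 and 13 lists, with 1 to 6 higher and 6 to 12 lower. The immediate early, ribosomal protein and p53 lists kept their calls in each of those fits. Over those fits the adjusted p ran from 4.287e-08 to 0.134 for DNA replication and from 3.469e-05 to 0.915 for stem cell identity. The DNA replication list turned to lower in HET with library weights (adjusted p = 0.453) and without HET 1 (6.942e-06), and missed the threshold when HET 1 was thinned (0.330), although its median barely moved (0.07, against 0.08). The stem cell identity list turned to higher without HET 1 (0.915) and was lost with library weights (0.202). The cause was not tested. Alternatives planned for normalised values (another pseudocount, no filter on low values) were not run, since the table holds counts. Depth limits genes of few counts, such as Gbp2b and Cpa3.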

Other observations

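Gene families were also tested by symbol, with 16 families chosen after the gene results had been seen, so they are not independent of the calls above. Circadian clock genes (15 tested) had a median log2 fold change of -0.37, with 14 negative values (camera adjusted p = 3.148e-06; adjusted p = 0.203 with an estimated correlation). Of these Per1, a repressor of the clock, fell from 489 ± 82.4 to 295 ± 54.6 CPM (SD, n = 3 each; edgeR adjusted p = 0.0236; 0.194 without WT 1, 0.0518 without WT 3 and 0.326 without HET 4). Nr1d2, Cry2, Tef and Bhlhe40 had all HET libraries below all WT libraries and did not pass, with log2 fold changes of -0.63, -0.43, -0.37 and -0.59. Arntl, the activator of the opposite phase, measured 28.0 ± 1.15 CPM in WT and 37.7 ± 10.6 CPM in HET (edgeR adjusted p = 0.980). It had the only positive value of the 15. The activator genes Clock and Npas2 had log2 fold changes of -0.02 ± 0.29 and -0.34 ± 0.56 (SE).

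Among 26 leucine zipper genes grouped by symbol, of the AP-1, CREB/ATF and related families, 5 fell (Junb, Cebpb, Maff, Fosl2 and Crem). Cebpb encodes a C/EBP factor, outside AP-1 and CREB/ATF. The group's median was -0.18 (camera adjusted p = 6.190e-07, and 0.122 with an estimated correlation). Crem, which encodes a cAMP-responsive modulator, fell from 29.3 ± 7.55 to 8.75 ± 3.38 CPM (SD, n = 3 each; edgeR adjusted p = 0.0190; 0.224 without WT 1, 0.101 without WT 4, 0.0737 without HET 3 and 0.206 without HET 4). All 6 RNA polymerase III transcripts listed, among them Rny1, Rmrp and Rn7sk, had negative values with a median of -0.40 and none passed (camera adjusted p = 3.025e-04; adjusted p = 0.576 with an estimated correlation). Rn7sk, Rpph1 and Rmrp are among the 5 most abundant genes, which also include Malat1 and Hsp90ab1. Together these 5 held 5.80%, 7.34% and 6.95% of the counts in WT 1, 3 and 4. In HET 1, 3 and 4 they held 5.14%, 7.48% and 6.23%, overlapping the WT values. The other 13 families were not called.

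In the following paragraphs, the depth and length tests and the counts over splits were fixed before their results were seen; the tests of handling, of time of day, of the Gbp2b paralogs, of the interferon list and of the regions around Gbp2b and Myc were chosen afterwards.

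The list of immediate early genes had a median log2 fold change of -0.43, with 4 of 32 members past the threshold and 9 positive values. Camera called it at the preset correlation only (adjusted p = 0.160 with an estimated correlation). A trend with length and GC as the whole cause is argued against by a median of -0.412 with the trend removed, still called at that preset. Fosl2 lost its own call there through a larger standard error, while its fold change was kept. With HET 1 thinned the median was -0.434 and the list was still called at that preset. Thinning keeps the expected share of each gene in its library, so it could hardly move the median. HET 3 and HET 4, with 4627452 and 5054028 total counts, lay within the WT range of 4249490 to 5600856. Their list levels were -0.50 and -0.82 relative to the WT mean, against -0.03 to 0.06 in the WT libraries. Without HET 1, the deepest library, the list's median was -0.29. These values argue against depth as the whole cause of the lower levels in HET 3 and HET 4. Handling or sorting that differed between the groups stays open. Of the heat-shock genes named for this question, Hspa1a and Hspa1b were not among the genes tested. The other 5 had a median of -0.205, just short of the bound set for them from the list's median. Their log2 fold changes ran from -0.275 for Hspe1 to 0.036 for Hsp90aa1. Collection at another time of day stays open too, since Arntl, Clock and Npas2 had a median of -0.0183 with a spread of 0.273, while 7 genes of the Per, Nr1d, Dbp and Tef type had -0.384 ± 0.0987. Loss of a Myc allele may also lower these genes, and neither this nor an effect of Cre itself, which only HET carries, could be told apart from handling here.

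The list of cytosolic ribosomal protein genes had a median of -0.24, with 0 of 72 members past the threshold and 14 positive values. Camera called it at the preset correlation only (adjusted p = 0.415 with an estimated correlation, and 0.241 by fry). The median was -0.247 with HET 1 thinned and -0.180 with the length and GC trend removed, and the list stayed called in both at that preset. The value with the trend removed argues against length and GC as the whole cause of the shift in the median. Thinning could hardly move the median, since it keeps the expected share of each gene. HET 3 and HET 4, whose total counts lay within the WT range, had list levels of -0.24 and -0.27, close to -0.25 in HET 1. The levels of WT 1, 3 and 4 were -0.16, 0.11 and 0.05. Without HET 1, the deepest library, the list's median was -0.28. These values argue against depth as the whole cause of the lower levels in HET 3 and HET 4. Whether the list differs beyond the correlation between its genes stays open. Lower Myc dose is a candidate explanation, since ribosomal genes are known MYC targets, but no test separated it from Cre or from differences between mice.

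Gbp2b was nearly absent from HET while its neighbour Gbp2 was not. Counted together, the pair had a log2 fold change of 0.0881 (95% interval -0.209 to 0.386), whereas loss of Gbp2b with no gain elsewhere would give -0.371, so reads assigned to the other paralog may account for the pattern, for example where the strains of origin differ in sequence. The interferon list showed no fall, with a median of 0.152, which speaks against a lower interferon response. This evidence is weak, since the list was not called with an estimated correlation (camera adjusted p = 0.637). The rule for it was also set after the median was known. Both groups carry the floxed allele, but a strain haplotype that differs between them, such as one carried with the transgene, stays open. Of 34 genes within 5 Mb, 2 (Metap1 and Gbp2) had an unadjusted edgeR p under 0.01, 5.88% against 1.55% of other genes (one-sided Fisher exact p = 0.0986). The window holds few genes, and Gbp2 counts may include reads of Gbp2b, so this share is not independent of the Gbp2b pattern. An effect of the Myc genotype was not tested separately.

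Within 5 Mb of Myc, with Myc and Pvt1 both left out, 1 of 27 genes (Trib1) had an unadjusted edgeR p under 0.01. This was 3.70% against 1.55% of other genes (one-sided Fisher exact p = 0.345). Trib1, which encodes a pseudokinase, measured 54.2 ± 7.22 CPM in WT and 30.4 ± 2.69 CPM in HET (SD, n = 3 each; edgeR adjusted p = 0.115).

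The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 28 genes, more than any other, the highest of which called 2, so 1 of the 10 splits gave as many. For gene lists the real split called 10 and the highest other 17, and 7 of the 10 splits called at least 10.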
